A study of Homo sapiens with 3 samples.

How the data were processed

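Total RNA of HepG2 cells, collected 72 h after transfection with 10 nM siRNA, was amplified, coupled to Cy5 and hybridised to one-colour arrays, per the labels' protocols. There were 3 arrays, 1 per group: control siRNA, villin siRNA and PTK7 siRNA. The labels name 2 villin siRNAs and do not say which was used for the array. Per the file headers, each scanner file holds a median intensity for each of 27456 spots, of which 24460 are probes and 2680 are blank spots. The scanner intensities are not normalised. The authors' deposited table holds intensities as whole numbers. They equal the spot median minus the blank mean, divided by a factor of 1.263, 1.601 and 1.337 on the 3 arrays, which sets each array's median to 25. All recomputed values lay within 1 unit of the deposited ones, and probes not above background have no value there.

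Background was the mean of the blank spots after leaving out 5% at each end: 60.77, 61.69 and 61.61 units, with SDs of 0.777, 0.759 and 0.732. The main setting was normexp with an offset of 50 followed by quantile normalisation across the 3 arrays, with limma 3.58.1 in R 4.3.3. The offset shrinks the differences of dim genes. The scanner files also have a background column per spot. It follows the spot signal (r = 0.983, 0.990 and 0.984 on the log scale), so it was used only in an alternative. A probe was detected if its spot median exceeded the blank mean by 2 SDs and the scanner had not flagged it; 5, 1 and 2 flagged probes were left out on the 3 arrays. The detected probes were exactly those with a value in the deposited table. The brightest probe stood for a gene with several.

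The platform annotation gave 20236 probes 1 gene symbol and none several, and 4224 probes were unnamed. Of the symbols, 17238 were current in the RefSeq table of assembly GRCh38.p14, 2899 were updated through a unique synonym and 99 were not matched. This gave 17559 genes, 2560 of them with more than 1 probe. No coordinates are given, since the files of the series name no genome build and no genomic probe positions, and the RefSeq table served for gene names only.

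With 1 array per group, differences are described by size. Genes at least 2-fold apart were counted among those detected on both arrays. Medians of 45 gene lists, fixed before the data were examined, were ranked among 10000 random lists drawn with replacement within 20 bins of mean level, and called outlying among the outermost 0.5% at either end. Among 45 lists of unrelated genes about 2.25 would lie beyond the 2.5 and 97.5 percentiles by chance, and 16, 9 and 17 did in the 3 comparisons. The lists are sets of related genes and some share members, such as ORM2, FGB and FGG in the secreted protein and acute phase lists. A single fluctuation of an array or culture can therefore move several lists, and 2.25 is no measure of chance for them. The counts of lists include 1 list whose result is not reported here. Named genes were VIL1 and PTK7; the 12 highest and 12 lowest per comparison with the control array (6 each for the others) among genes above the median level of 6.69; up to 4 members of each outlying list or list with 3 members beyond 1.5-fold; and the 3 highest bounds of genes detected on 1 array. A bound is the brighter value over the lowest detected signal, or the dim probe's own if higher. Genes added after their values were seen are the few that counts or lists of 5 or fewer single out. For the shared direction, 100 simulations of 3 unchanged arrays used level-dependent noise from the difference of the villin siRNA array and the array labelled PTK7 siRNA.

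Alternatives fixed beforehand were median scaling, cyclic loess, the deposited values, plain subtraction of the blank mean, no background correction, no filter or a stricter filter on dim probes, the mean of a gene's probes, a 1.5-fold threshold, unmatched random lists and list means. After seeing the data 2 were added: normexp with the background column, and scaling to the surroundings on the slide. The latter divides the signal above blank by the local median deviation of that array from the mean of the 3 (window of 11 columns by 5 rows within a block) before normexp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

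The procedure was tested on simulated arrays with 200 changed probes. In the brighter part of the probes 3, 15, 20 and 21 of 25 probes with a true 2-, 3-, 4- and 8-fold change of a simulated array against a simulated control array were called, in the dimmer part 2 and 6 of 25 with 4- and 8-fold, and none of 21010 unchanged probes. The simulated noise was the log2 SD of positive control spots within the control array, 0.128, plus the SD of the blank spots. It holds no variation between arrays or cultures, so the lack of calls among unchanged probes gives no false call rate for the data. A true 4-fold change was measured as 3.11-fold in the brighter and 1.24-fold in the dimmer part. With a simulated gradient along the slide, the correlation of the differences with the gradient was 0.57 before and 0.01 after position scaling, and 67 of the 200 changed probes were called after it, 66 before it and 67 without a gradient. The simulated gradient was constant within each block, so a local median taken within a block removes it by construction. Unevenness within blocks, as along rows or edges, was not simulated. Of 40 simulated lists shifted by 0.3, all 40 were outlying. This shift is larger in size than any list median reported below, of which the largest was -0.287, so shifts of the observed sizes were not tested.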

Results

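Gene expression was measured in HepG2, an established human hepatocellular carcinoma line, 72 h after transfection with 10 nM of a control siRNA, an siRNA against villin (VIL1, an actin-bundling protein of microvilli) or an siRNA against PTK7 (a receptor-like pseudokinase of Wnt and planar polarity signalling). Each group had 1 one-colour array, so none of the differences has a replicate check, no significance test of a difference was run, and each value describes these 3 arrays. Of 24460 probes, 22090 (90.3%) were above background on the control array, 22525 (92.1%) on the villin siRNA array and 22064 (90.2%) on the array labelled PTK7 siRNA. The median signal of these probes above the blank spots was 31.6, 40 and 33.4 units, and 15697 genes were detected on all 3 arrays. The number of arrays limits the precision of every value.

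The targeted transcripts were examined first. In the authors' deposited table VIL1 had an intensity of 924 on the control array, 129 on the villin siRNA array and 1084 on the array labelled PTK7 siRNA, where each array has a median of 25. In the normalised values VIL1 was 5.66-fold lower on the villin siRNA array than on the control array (log2 difference -2.50) and 0.28 higher on the array labelled PTK7 siRNA. PTK7 is represented by a single dim probe, with deposited intensities of 14, 25 and 12 in the same order. Its normalised log2 difference was -0.05 on the array labelled PTK7 siRNA and 0.24 on the villin siRNA array, so this probe did not show a reduction of 2-fold against the control array. Against the villin siRNA array it was lower by 0.30, and 2.08-fold in the deposited values, in the direction of the label. On the control array the spot lay 23.2 SDs of the blank spots above their mean. With a cutoff of 2 SDs above that mean, 90.3% of all probes were detected there. The distance from the blank spots therefore does not show how much of the signal was PTK7 transcript. Every direction given for the array labelled PTK7 siRNA is therefore that of an array whose knockdown the normalised values do not show against the control array. The PTK7 spot lies in block 24 of the slide, among the blocks with high differences against the control array. After each array was scaled to its surroundings on the slide, the PTK7 log2 difference against the control array was -0.18. With plain subtraction after scaling, without normexp and its offset, it was -0.67 (1.59-fold lower), against -0.22 for plain subtraction of the blank mean without scaling. The scaled and subtracted signal was 2.04-fold lower than on the villin siRNA array. Of 785 genes of like level, 6 had a value as low as -0.67 or lower. This setting was chosen after the values were seen, and no such rank is given for the other settings.

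**Figure D1:**
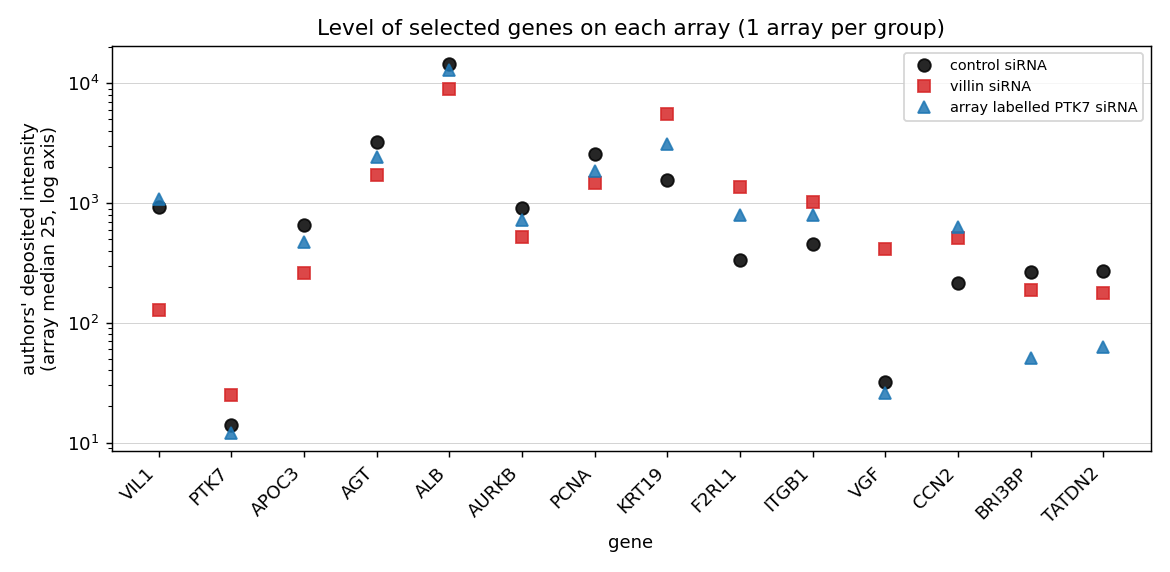
Intensities from the authors' deposited table (log axis, each array with a median of 25) for 14 genes, with 1 point per array. VIL1 lies at 129 on the villin siRNA array against 924 and 1084 on the control array and the array labelled PTK7 siRNA, and PTK7 lies between 12 and 25 on all 3.

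The differences against the control array followed the position of the spots on the slide. The median log2 difference of a block of spots ran from -0.11 to 0.12 for the villin siRNA array and from -0.12 to 0.15 for the array labelled PTK7 siRNA, and only from -0.03 to 0.04 between these 2 arrays. Log2 differences of adjacent spots correlated across probes with r = 0.31, 0.48 and 0.15, respectively, where probes are not independent replicates. Counts and leading genes are therefore also given after each array was scaled to the surroundings of each spot (position scaling), a setting chosen after seeing the data.

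**Figure D2:**
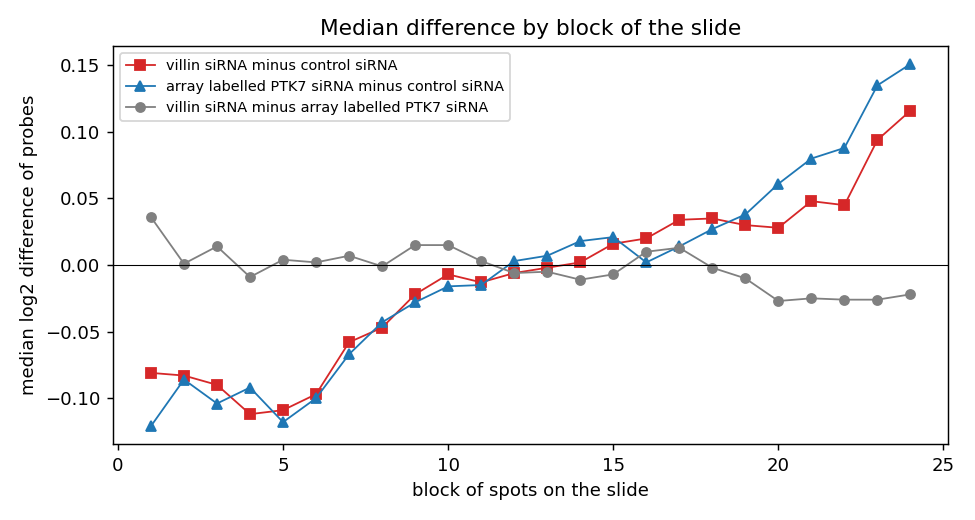
Median log2 difference of the probes in each of the 24 blocks of the slide, for the 3 pairs of arrays. Both comparisons against the control array climb along the slide, to 0.12 and 0.15, while the comparison between the villin siRNA array and the array labelled PTK7 siRNA stays between -0.03 and 0.04.

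The comparison of the villin siRNA array with the control array asks which transcripts differ where villin is reduced. After VIL1, the lowest transcript was APOC3, an apolipoprotein of hepatocyte-derived lipoproteins, which was 2.31-fold lower (1.95-fold after position scaling). The highest was VGF, a neuroendocrine secretory protein precursor, at 6.42-fold (deposited intensities 32 and 414; 6.93-fold after scaling). This direction turned with the background column, to a log2 difference of -0.18 for VGF. KRT19, a keratin of biliary and progenitor epithelium, was 3.58-fold higher (2.55-fold after scaling). The calcium-binding protein S100A2 was 3.40-fold higher, the transcription factor SOX4 2.73-fold and the cytokine IL11 2.70-fold, with 3.21-fold, 2.62-fold and 2.51-fold after scaling. Among 15907 genes detected on both arrays, 46 were at least 2-fold higher and 2 (VIL1 and APOC3) at least 2-fold lower, while 97.9% lay within 1.5-fold. Of the 46 higher genes, 29 lay in blocks 19 to 24 of the slide, which held 4004 of the 15907 genes. After position scaling 30 were higher, of which 27 were among the 46, and 2 were lower, VIL1 and the homeobox gene PBX2. Of these 30, 15 still lay in blocks 19 to 24. The authors' deposited values, which differ in background correction, offset, scaling and rounding, gave 591 higher and 289 lower genes, and plain subtraction of the blank mean gave 354 and 142. Of the 48 genes, 5 had several probes. All probes of these 5 pointed the same way, but in only 2 of them did all probes differ by at least 1.5-fold.

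PDCD10, F2RL1, a protease-activated receptor, and EEF1B2, a translation elongation factor subunit, ranked directly after VGF, higher by 2.13, 1.93 and 1.86 on the log2 scale. After position scaling these values were 1.89, 0.99 and 1.52. EEF1B2 lay at only 10 in the authors' deposited table on the control array against 136. RAB3B and KRTAP3-1 were both higher by 1.56, and PSMD2 by 1.54, with RAB3B at 1.27 and PSMD2 at 0.65 after scaling. SELPLG was 2.83-fold higher, with a log2 difference of 0.70 after scaling. The remaining lowest genes lay between -0.98 and -0.82 and comprised HOXD1, GNPDA1, PBX2, ODAM, FADS1, AGT, TOMM22, NUPR1, ZCCHC2 and FGL1. A second probe of HOXD1 lay at -0.23, against -0.98 for the brighter one. AGT, the angiotensin precursor made by hepatocytes, was 1.82-fold lower (1.49-fold after scaling). The highest bounds for genes detected on 1 of these 2 arrays were small, at least 1.34-fold for MCHR2 on the villin siRNA array and at least 1.69-fold for TMPRSS11F on the control array.

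Of 45 gene lists fixed before the data were examined, 11 were outlying, with a median among the outermost 0.5% at either end of 10000 random lists matched on level, which describes these arrays only. Cell cycle lists lay low. The median of 29 mitosis genes was -0.287, below all 10000 random lists, with 24 members below 0, among them the kinases AURKB (-0.73) and TTK (-0.67), cyclin CCNB2 (-0.63) and KIF20A (-0.49). For 27 genes of G1/S and DNA replication the median was -0.224, below all random lists, with 22 members below 0, among them CDT1 (-0.73), PCNA (-0.69), RRM1 (-0.59) and MCM2 (-0.51). After position scaling the medians were -0.257 and -0.203, and both lists stayed outlying, with AURKB at -0.43, CCNB2 at -0.34, CDT1 at -0.47 and PCNA at -0.40.

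Some stress-response and hepatocyte lists also lay low. Targets of ATF4, the transcription factor of the amino acid response, had a median of -0.248, below all random lists, with NUPR1 at -0.84, SLC7A5 at -0.67, the serine synthesis enzyme PHGDH at -0.59 and DDIT3 at -0.55. Targets of NRF2, the regulator of the oxidative stress response, had a median of -0.196 (percentile 0.11), with HMOX1 at -0.68 and NQO1 at -0.59. The acute phase list had a median of -0.139 (percentile 0.14), with ORM2 and the hepcidin gene HAMP at -0.52. Among 25 hepatocyte secreted proteins the median was -0.166 (percentile 0.27), with APOC3 at -1.21, AGT at -0.87, ITIH2 at -0.58 and ALB, encoding albumin, at -0.56. The secreted protein list had a median of -0.102 (percentile 1.12) after position scaling and was then no longer outlying, with ITIH2 at -0.22 and ALB at -0.38. The ATF4, NRF2 and acute phase lists stayed outlying, at -0.256, -0.199 and -0.093, with SLC7A5 at -0.32 and NQO1 at -0.35. With the deposited values the secreted protein and acute phase lists were no longer outlying, nor were the NRF2 and acute phase lists with plain subtraction. The acute phase list was also lost with median scaling, the NRF2 list with the mean of probes, and the secreted protein list without background correction or without the filter on dim probes. With the background column none of the 11 lists was outlying. Other hepatocyte lists were not outlying on the villin siRNA array: coagulation and complement (-0.038, percentile 25.04), hepatocyte transcription factors (-0.128, percentile 2.51) and fetal liver markers (-0.005, percentile 62.71).

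Adhesion lists lay high. Epithelial junction and keratin genes had a median of 0.104 (percentile 99.91), with KRT19 at 1.84, CLDN4 at 0.88, E-cadherin CDH1 at 0.78 and N-cadherin CDH2 at 0.57. Extracellular matrix and integrin genes had a median of 0.078 (percentile 99.91), with the integrin subunits ITGA2 at 1.23, ITGB1 at 1.12 and ITGAV at 0.83 and the protease inhibitor TIMP1 at 0.75. Both lists stayed outlying after position scaling, where ITGA2 lay at 0.79, ITGB1 at 0.57, ITGAV at 0.45, CDH1 at 0.52 and CDH2 at 0.29. The matrix and integrin list was no longer outlying with median scaling or the mean of probes, nor the junction list with genes above the median level only. The bile canaliculus list had a median of 0.082 (percentile 99.90), which became 0.035 (percentile 97.74) after scaling. It was also no longer outlying with median scaling, the deposited values, genes above the median level only or list means. Of the lists for other cell types, immune markers had a median of 0.097 (percentile 99.62) over 11 detected genes, led by LYZ at 0.89 (0.93 after scaling), and the list median became 0.011 (percentile 78.83) after scaling. The immune list stayed outlying only with median scaling, cyclic loess and the mean of probes. The squamous epithelium list, which holds S100A2, had a median of 0.059 (percentile 97.21). The reference gene list had a median of 0.020 (percentile 74.41).

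Some lists had members beyond 1.5-fold and were not outlying. Among YAP and TEAD targets (median 0.021, percentile 80.26) the matricellular genes CCN2 and CCN1 lay at 1.09 and 0.85 and NT5E at 1.08, while the transcription factor TEAD4 lay at -0.64. After position scaling CCN2 lay at 0.27, CCN1 at 0.63, NT5E at 1.20 and TEAD4 at -0.46. Drug and bile acid metabolism genes were just short of outlying, with a median of -0.068 (percentile 0.61; -0.026 and percentile 12.20 after scaling), and held SULT2A1 at -0.70 and CYP1A1 at 0.56 (0.25 after scaling). Fatty acid synthesis and lipid storage genes had a median of -0.002 (percentile 65.07), with FADS1 at -0.87, MLXIPL at -0.77, FASN at -0.59 and ACLY at 0.63. The lists of villin family members and of microvillus genes had medians of -0.008 (percentile 55.78) and 0.029 (percentile 88.66).

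**Figure D3:**
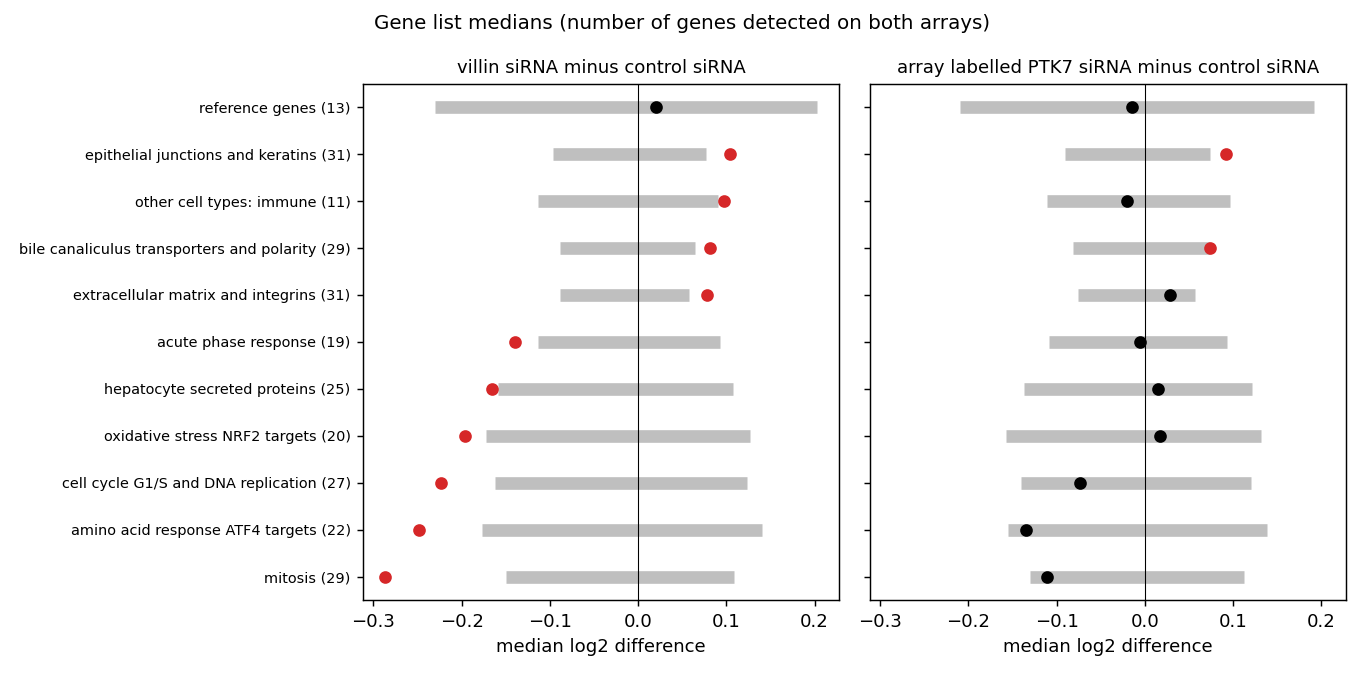
Median log2 difference of the described gene lists that were outlying in either comparison against the control array, and of the reference genes, with the number of genes detected in brackets. Grey bars span the medians of 10000 random lists matched on level without the outermost 0.5% at either end, red points lie outside the bars, and mitosis genes lie at -0.287 on the villin siRNA array.

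The comparison of the array labelled PTK7 siRNA with the control array asks the same question for PTK7. The lowest transcripts on the array labelled PTK7 siRNA were BRI3BP, 3.39-fold lower (3.33-fold after position scaling), and TATDN2, 3.02-fold lower (2.34-fold after scaling). The highest were PDCD10 at 3.95-fold, AKR1A1, an aldehyde reductase, at 3.07-fold, and EEF1B2 at 2.67-fold, with 3.33-fold, 2.96-fold and 2.19-fold after scaling. With the background column 3 of these directions turned, to 0.12 for BRI3BP, 0.04 for TATDN2 and -0.54 for PDCD10. CCN2 was 2.63-fold higher, but 1.37-fold after scaling. Among 15775 genes detected on both arrays, 17 were at least 2-fold higher and 2 (BRI3BP and TATDN2) at least 2-fold lower, and 99.0% lay within 1.5-fold. Of the 17 higher genes, 16 lay in blocks 19 to 24 of the slide. After position scaling 3 genes were higher (PDCD10, AKR1A1 and EEF1B2) and the same 2 were lower. The authors' deposited values gave 364 higher and 435 lower genes, and plain subtraction gave 252 and 188. SCCPDH, at 1.24, had a second probe that went the other way, at -0.07.

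Further genes at the top were GLG1 (1.29), PEG3-AS1 (1.22), SELPLG (1.17), F2RL1 (1.15), RTN3 (1.06), PSMD2 (1.05) and EXOSC6 (1.05). After position scaling all of these lay between 0.03 and 0.56, and with the background column GLG1 and PSMD2 lay at -0.03 and -0.05. Those at the bottom were EIF4H (-0.98), RPL10L (-0.90), the RNA acetyltransferase gene NAT10 (-0.83), the cationic amino acid transporter gene SLC7A1 (-0.81), SNTB1 (-0.75), DENND4B (-0.74), TGFBR3 (-0.74), PPP1R14A (-0.73), KRTAP4-8 (-0.72) and FRMD1 (-0.72). FRMD1, SLC7A1 and EIF4H lay at -0.86, -0.76 and -0.67 after scaling, and NAT10 at -0.25. The spots of FRMD1 and SLC7A1 lie in the last row of their blocks. A second probe of PPP1R14A lay at 0.13. On the array labelled PTK7 siRNA the highest bound for a gene detected on 1 array was at least 1.68-fold, for TMPRSS11F on the control array, again limited by the offset.

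On the array labelled PTK7 siRNA, 3 lists were outlying against the control array, of which 2 are described. Epithelial junction and keratin genes had a median of 0.092 (percentile 99.85), and 0.098 after scaling, with KRT19 at 1.01, EPCAM at 0.71 and CLDN3 at 0.50, or 0.46, 0.28 and 0.11 after scaling. This list was no longer outlying with the deposited values, plain subtraction or the background column. Bile canaliculus genes had a median of 0.074 (percentile 99.52), and 0.053 after scaling, with CEACAM1 at 0.68 (0.22 after scaling). This list was no longer outlying with median scaling, the deposited values, plain subtraction, genes above the median level only, list means or the background column. The lists nearest to the target, Wnt planar cell polarity, canonical Wnt targets and Wnt and beta-catenin components, had medians of -0.002, -0.018 and -0.021 (percentiles 59.78, 40.70 and 33.85). Extracellular matrix and integrin genes had a median of 0.029 (percentile 93.94), with ITGA2 at 0.80 and ITGB1 at 0.76, or 0.39 and 0.13 after scaling. Immune and squamous markers had medians of -0.020 and -0.021. Mitosis genes had a median of -0.111 (percentile 1.30), ATF4 targets -0.135 (percentile 1.37) and G1/S genes -0.074 (percentile 10.68), none of them outlying. After scaling these medians were -0.025, -0.169 and -0.112, and the ATF4 and G1/S lists were then outlying. NRF2 targets lay at 0.017 (-0.059 after scaling, not outlying), acute phase genes at -0.006 and hepatocyte secreted proteins at 0.015.

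Set against each other, the villin siRNA array and the array labelled PTK7 siRNA differed by at least 2-fold in 9 of 15947 genes, 8 higher and 1 (VIL1) lower on the villin siRNA array. After position scaling 5 were higher and 1 lower. The authors' deposited values gave 402 higher and 182 lower, and subtraction gave 131 and 77. VIL1 was 6.89-fold lower on the villin siRNA array, VGF 7.05-fold higher, BRI3BP 2.49-fold, IL11 and S100A2 2.25-fold and TATDN2 2.08-fold higher. RCN1 was higher by 1.05 on the log2 scale, GNPDA1 was 1.99-fold lower, and TOMM22, DCAF12, ACTA1 and PNRC2 lay between -0.94 and -0.85. With the background column VGF, BRI3BP, TATDN2 and RCN1 turned, to -0.21, -0.11, -0.06 and -0.38.

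In this pair, which does not involve the control array, 9 lists were outlying on the low side and 3 on the high side of the villin siRNA array. Hepatocyte secreted proteins had a median of -0.259, with APOC3 at -0.79, and 21 of 25 members were below 0. Coagulation and complement genes had a median of -0.115, acute phase genes -0.168, mitosis genes -0.157, G1/S genes -0.147 and interferon-stimulated genes -0.079, all below every one of 10000 random lists. NRF2 targets (-0.140, percentile 0.07), ATF4 targets (-0.123, percentile 0.22) and unfolded protein response genes (-0.104, percentile 0.24) were also low. On the high side were extracellular matrix and integrin genes (0.064, percentile 99.99, TIMP1 at 0.95), apoptosis genes (0.085, percentile 99.97, PMAIP1 at 0.39 and BCL2L1 at 0.30, but CASP6 at -0.51) and immediate early genes (0.063, percentile 99.82, KLF6 at 0.52). Of these 12 lists, 11 stayed outlying after position scaling, all except the unfolded protein response, at percentile 0.87. With genes above the median level only, and with list means, the interferon, unfolded protein response and apoptosis lists were no longer outlying. The matrix and apoptosis lists were lost with median scaling, the NRF2, matrix and immediate early lists with the mean of probes, and all except the secreted protein and mitosis lists with the background column. In the interferon list ISG20 lay the other way, at 0.88. Squamous and immune markers had medians of 0.066 (percentile 98.98) and 0.024 (percentile 89.63), with S100A2 at 1.17. After position scaling both marker lists were outlying, at 0.086 (percentile 99.86) and 0.063 (percentile 99.77), beside the high lists of extracellular matrix, apoptosis and immediate early genes. So were p53 targets (0.082, percentile 99.97), metallothionein and zinc genes (0.108, percentile 99.92) and mesenchymal transition genes (0.049, percentile 99.71), from 0.061, 0.078 and 0.042 before scaling.

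The differences of both siRNA arrays against the control array went largely the same way, with the caveat that the normalised values do not show PTK7 knockdown against the control array. Of the genes at least 2-fold higher, 11 were higher on both the villin siRNA array and the array labelled PTK7 siRNA, and none was at least 2-fold lower on both. The absence of shared lower genes depended on the setting, since 104 were lower on both with the deposited values, 35 with plain subtraction, 134 with the background column, 6 with the mean of probes and 1 without the filter on dim probes. PDCD10, EEF1B2, AKR1A1, SELPLG, F2RL1 and GLG1 ranked highest in common, and HOXD1 (-0.98 and -0.72), FADS1 (-0.87 and -0.64), the DNA ligase LIG1 (-0.68 and -0.61), SLC16A13, OSGIN1 and PCGF2 lowest. After position scaling F2RL1 lay at 0.99 and 0.11, GLG1 at 0.19 and 0.22, LIG1 at -0.50 and -0.33 and PCGF2 at -0.30 and -0.25. Across 15697 genes the Pearson correlation of the log2 differences was 0.740 and Spearman's 0.724. Genes are not independent replicates, and both comparisons share the 1 control array. Simulated unchanged arrays that share a control gave a correlation of 0.502 and no shared 2-fold gene, and independent lists would share 0.05 genes. The covariance was 0.0284 against a simulated 0.0067, and the control array cannot be split, so part of the excess may come from the shared control array. After position scaling the correlation was 0.631 (simulated 0.501), the covariance 0.0128 (simulated 0.0049), and 3 genes, PDCD10, AKR1A1 and EEF1B2, were higher on both.

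**Figure D4:**
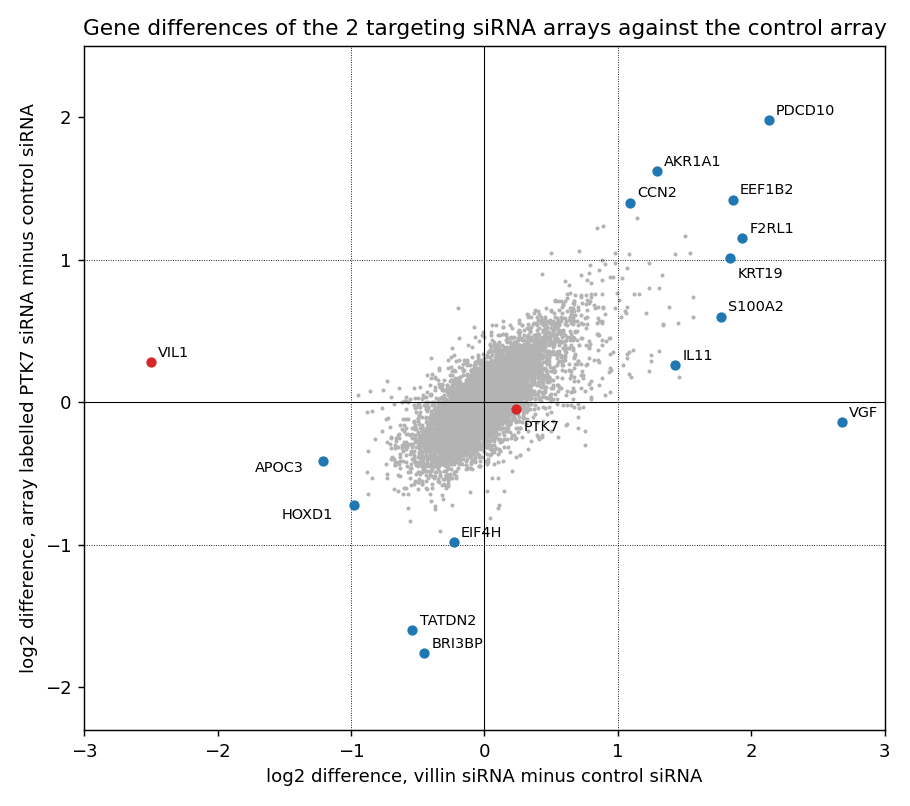
Log2 difference of each of 15697 genes on the villin siRNA array (horizontal axis) and on the array labelled PTK7 siRNA (vertical axis), both against the control array, with dotted lines at 2-fold. VIL1 lies at -2.50 and VGF at 2.68 on the horizontal axis alone, PDCD10 lies at 2.13 and 1.98, and BRI3BP at -1.76 on the vertical axis.

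Set beside the other arrays in turn, at 1.5-fold the control array was lower than both others in 99 genes and higher in 7. The villin siRNA array was higher than both others in 53 genes and lower in 18, and the array labelled PTK7 siRNA in 1 and 8. After position scaling the control array was lower in 16 genes and higher in 2, while the villin siRNA array was higher in 53 and lower in 14.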

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

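The count of unnamed probes was chosen after the data had been seen. Probes without a gene name lie outside the comparisons above, and some were well above the control array. On the villin siRNA array 8 unnamed probes of 3709 detected were at least 2-fold higher than on the control array, the highest by 2.17 on the log2 scale. On the array labelled PTK7 siRNA 4 of 3654 were, the highest by 2.18. None was at least 2-fold lower in either comparison.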

How the results depend on the processing

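The background column and the position scaling were chosen after seeing the data. With 1 array per group no array could be left out and no paired analysis was possible because there are no replicates. Signal over background limits the gene counts: the median detected probe lay 31.6 to 40 units above blank, below the offset of 50. All 189 differences of named genes kept their sign under median scaling, cyclic loess, the deposited values, subtraction, no background correction and the mean of probes; 188 did under position scaling and 125 with the background column. Counts for villin siRNA against control, the array labelled PTK7 siRNA against control, and the villin siRNA array against that array are given in this order, higher then lower.

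The deposited values gave 591 and 289, 364 and 435, and 402 and 182 genes; subtraction gave 354 and 142, 252 and 188, and 131 and 77. Neither has normexp or an offset, and the deposited values also have 1 scale factor per array and are rounded; these parts were not varied singly. The background column gave 208 and 307, 360 and 314, and 202 and 347, and the 1.5-fold threshold 253 and 83, 128 and 34, and 78 and 27. Position scaling gave 30, 3 and 5 higher genes. The mean of probes gave 14 lower, 12 lower, and 13 higher and 9 lower, and median scaling 14 higher in the third. Genes higher on both siRNA arrays numbered 265 (deposited values), 157 (subtraction), 119 (background column) and 3 (position scaling). Genes lower on both, 0 in the main values, numbered 104, 35 and 134 with the deposited values, subtraction and the background column, 6 with the mean of probes and 1 with no filter. The correlation between comparisons was 0.490 with the background column and 0.631 with position scaling. VIL1 lay at -2.84 (deposited values), -2.82 (subtraction), -1.09 (background column) and -2.21 (position scaling).

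With the background column, which follows the spot signal, 64 of the 189 differences turned sign, and the 10 of these that had been at least 2-fold are given here. Under position scaling 1 did, CD79A on the villin siRNA array against control, from 0.18 to just below 0. Against control, VGF lay at -0.18 on the villin siRNA array; on the array labelled PTK7 siRNA PDCD10 lay at -0.54, GLG1 at -0.03, PSMD2 at -0.05, BRI3BP at 0.12 and TATDN2 at 0.04. Between the siRNA arrays VGF lay at -0.21, BRI3BP at -0.11, TATDN2 at -0.06 and RCN1 at -0.38. List medians turned to 0.009 (acute phase, villin siRNA against control) and, between the siRNA arrays, 0.003 (interferon-stimulated genes), 0.019 (unfolded protein response), 0.016 (ATF4 targets) and -0.035 (immediate early genes). Beyond what these constructions show, the cause was not tested.

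Of the 11 lists outlying on the villin siRNA array, 11 stayed so under cyclic loess, 8 under position scaling, median scaling and subtraction, 7 with the deposited values and 0 with the background column. It was 10 with unmatched random lists, 9 with no background correction, the mean of probes, no filter on dim probes and list means, and 8 with genes above the median level only. Of the 3 on the array labelled PTK7 siRNA, 3 stayed so under cyclic loess, no background correction, the mean of probes, no filter and unmatched random lists. It was 2 under position scaling and median scaling, 1 with the deposited values, subtraction, genes above the median level only and list means, and 0 with the background column. Of the 12 between the siRNA arrays, 12 stayed so under cyclic loess, the deposited values, subtraction, no background correction, no filter and unmatched random lists. It was 11 under position scaling, 10 under median scaling, 9 with the mean of probes, genes above the median level only and list means, and 2 with the background column.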

Other observations

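The position scaling, the test of an exchange of arrays and the test of the surroundings of the PTK7 spot were chosen after the values were seen. Cholesterol synthesis genes had medians of -0.164 on the villin siRNA array (percentile 0.76) and -0.121 on the array labelled PTK7 siRNA (percentile 1.87), and became outlying after position scaling at -0.124 (percentile 0.44) and -0.114 (percentile 0.11). Interferon-stimulated genes had a median of 0.050 on the array labelled PTK7 siRNA (percentile 97.17; 0.055 and percentile 99.92 after scaling), with IFI6 at 0.57 (0.40 after scaling). Metallothionein and zinc genes had a median of 0.114 on the villin siRNA array (percentile 97.89; 0.118 and percentile 99.62 after scaling). Unfolded protein response genes had a median of -0.130 on the villin siRNA array (percentile 1.02), and -0.157, below all 10000 random lists, after scaling. After scaling, 3 further lists were outlying on the array labelled PTK7 siRNA: ATF4 targets (-0.169), G1/S genes (-0.112) and extracellular matrix and integrin genes (0.044). CYP1A1, an aryl hydrocarbon receptor target, lay 0.56 and 0.57 above control on the 2 siRNA arrays (0.25 and 0.32 after scaling), and its second probe 1.14 and 1.11.

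The first pattern is that both siRNA arrays differ from the control array the same way. Spots adjacent to the 106 genes at least 1.5-fold apart on the control array deviated the same way, by a median of 0.274 (95% bootstrap interval 0.231 to 0.302) against 0.773 for the genes themselves, so uneven hybridisation of the control array may account for part of it. After position scaling the correlation, 0.631, was still above the highest of 100 simulations of unchanged, equally noisy arrays, 0.519. This argues against unevenness as the whole of it only if the control array was no noisier than the others and scaling removed all unevenness. Neither is settled. One set of positive control spots had a log2 SD of 0.241 on the control array against 0.131 and 0.209 on the villin siRNA array and the array labelled PTK7 siRNA. The other set had 0.128 against 0.120 and 0.127. After scaling the robust SD of the differences was 0.090 and 0.082 against the control array and 0.071 between the siRNA arrays. With 1 control array, a control array or culture that was noisier or stood apart as a whole cannot be told apart from a response common to both targeting siRNAs. PDCD10, AKR1A1 and EEF1B2, which stayed at least 2-fold higher on both, all lie in row 10 of the 10 rows of their blocks. So do BRI3BP, SLC7A1, FRMD1, PPP1R14A and KRTAP4-8, among the lowest on the array labelled PTK7 siRNA, and TOMM22 and ZCCHC2, among the lowest on the villin siRNA array. The other genes named as highest or lowest on either array against control lie in other rows. Of these, F2RL1, KRT19, RAB3B, PSMD2, SOX4, CCN2 and GLG1 among the highest lie in row 1, the opposite edge. APOC3, HOXD1, FADS1, AGT and SNTB1 among the lowest lie there too. The share of all genes in these edge rows is not given here, and an effect of either edge row was not tested.

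The second pattern is that PTK7 was only slightly lower on the array labelled PTK7 siRNA than on the control array (-0.05), though 2.08-fold lower than on the villin siRNA array in the deposited values and 2.04-fold after scaling and plain subtraction. An exchange of the 2 siRNA arrays is argued against by VIL1, which was at -2.78 on the villin siRNA array relative to the other. Uneven hybridisation around the PTK7 spot may have hidden a reduction: after scaling to the surroundings and plain subtraction PTK7 was at -0.67 against control, short of the 2-fold reduction set as the bound. This account stays open, since only such a difference above -0.25 would have excluded it, and background correction and position both enter (-0.18 for scaled PTK7 with normexp and its offset, -0.22 for plain subtraction without scaling). Signal of another transcript on the probe stays open, because the array has 1 PTK7 probe, as does, untested, a transcript that this siRNA lowered little at 72 h.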
